A study of Mus musculus with 8 samples.

How the data were processed

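Poly(A)-selected RNA from mouse V6.5 embryonic stem (ES) cells was sequenced in 8 libraries, 2 in each of 4 groups. V6.5 is a C57BL/6 by 129 hybrid ES cell line, and per the labels' protocols it was grown in 2i medium, which holds inhibitors of MEK and GSK3. In a line in which OCT4 is fused to the FKBP degradation tag (OCT4-FKBP), cells received DMSO or a dTAG compound for 24 h. In the untagged parental line (WT), LIF was present or had been withdrawn for 5 days. Libraries were made with a strand-marking Illumina kit and read from one end, per the labels' protocols. The labels do not say that replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

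The authors deposited raw read counts per RefSeq transcript accession, in 1 table per library; HISAT2, HTSeq and the mm9 genome build are named per the submitters' processing notes, without versions. The strand setting of the counting is not given in the sources used here. Each table held 41565 accessions plus HTSeq's summary lines, which were kept out of library sizes and tests. A read in sequence that several accessions of a gene share is assigned to no accession in this kind of counting, and the ambiguous reads came to 42.5% of counted plus ambiguous reads over the 8 libraries. Reads without a feature made up 10.4% to 14.9% of uniquely aligned reads. Genes with 1 accession carried 95.5% of the counted reads, and the 7990 genes with 2 or more accessions carried 3.8%. Nanog (4 accessions), Stat3, Myc and Gata4 had 0 reads in total over the 8 libraries, Esrrb had 1 and Gapdh had 57. For such genes a low count says nothing about expression, and for tested genes with several accessions, such as Pou5f1, the values cover only the sequence that tells the accessions apart.

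Of the accessions, 41451 were paired with a gene symbol, 41325 through the RefSeq table of assembly GRCm38 and 126 through the GENCODE table, and 114 without a symbol kept their accession as a name. The tables were used for names only, because their build differs from mm9, and no coordinates were taken from them. Counts were summed over the accessions of a symbol. The design had assumed counts per gene, so this sum was chosen after the files had been seen to hold transcripts. The 2 added alternatives, also chosen after seeing the data, tested each accession alone or only genes with 1 accession.

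Library totals ranged from 7221451 to 11447468 counted reads. Gene counts were analysed in edgeR 4.0.16 (R 4.3.3) with TMM scaling, filterByExpr, glmQLFit and glmQLFTest, in one fit of the 4 groups over all 8 libraries, with 4 residual degrees of freedom. The filter left 10311 genes, of which 8026 had 1 accession. The biological coefficient of variation was 4.4%. Adjusted p-values are Benjamini-Hochberg values over all tested genes, with calls at 0.05; standard errors of log2 fold changes are the fold change divided by the square root of its F statistic. CPM values are scaled by edgeR to the TMM-adjusted library size. The comparisons were dTAG against DMSO, no LIF against LIF, the difference between these 2 responses, and the tagged line in DMSO against the parental line with LIF. The first 2 comparisons use separate control libraries. The tag, the clone, the DMSO and any culture batch cannot be told apart in the last one.

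The rules below were fixed before the data were examined. Named genes were Pou5f1, Sox2, Nanog, Klf4, Esrrb and Med1, then the 5 largest changes each way at an adjusted p of 0.05, with a mean of at least 5 CPM and both libraries of one group beyond both of the other. Members with the smallest adjusted p were added, 2 for each of 8 main gene lists and 1 for each of 14 other lists. The difference of responses took 5 genes each way, with the CPM minimum over all 8 libraries, and the comparison of control groups 3 each way; 1 gene taken by the rule for the difference is not reported here. The main lists were core and general pluripotency, naive pluripotency, formative and primed pluripotency, trophoblast, primitive endoderm, primitive streak and early mesoderm, neural ectoderm, and LIF-STAT3 targets. The other lists were FGF-ERK feedback targets, Wnt targets, TGF-beta, Nodal and BMP targets, the two-cell-like state, germline genes, imprinted genes, Mediator and coactivators, p53 targets, glycolysis and hypoxia, cholesterol synthesis, G2 and M phase, immediate early and heat shock genes, the integrated stress response, and fibroblast and smooth muscle genes. Lists with at least 5 tested members, 21 of 22, were tested as sets with camera (limma 3.58.1), with a preset inter-gene correlation of 0.01 and, as an alternative, an estimated one.

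Where a group held 0 reads of a gene, the fold is a lower bound against a floor of 3 reads over that group's libraries; at 1 to 3 reads the ratio is given with an exact 95% interval. Floors and intervals cover counting error only. Both replicates of each group differed by more than sampling noise, with chi-square values per gene of 1.85 to 4.97, so no library was a copy of another. On simulated data, the dTAG comparison recovered 82.4%, 92.4% and 98.5% of genes changed by 0.5, 1 and 2 on the log2 scale, with 0.17% of unchanged genes called, in a step on 10071 genes. The LIF comparison recovered 79.4%, 95.5% and 100% with 0.05% of unchanged genes called, on 9616 genes. In each simulation 68, 66 and 66 genes with a mean above 5 CPM were changed by these sizes, and the trophoblast list was also raised. Counts were drawn with the spread fitted to the data. Recovery at lower counts, and changes as widespread as in the real data, were not covered. Alternatives were DESeq2 size factors (RLE) in edgeR, no filter, a filter of 5 CPM in 2 libraries, each library left out in turn, a replicate block, the DESeq2 1.42.0 Wald test, and a fit of only the 4 libraries of a comparison. Tables and figures were made with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.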

Results

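RNA-seq counts were analysed for 8 libraries of mouse V6.5 ES cells, which the study used to follow gene expression after loss of the transcription factor OCT4 or after withdrawal of the cytokine LIF. The OCT4-FKBP line carries OCT4 fused to FKBP, a tag through which a dTAG compound brings the fusion protein to the cell's degradation machinery. Both of its groups, DMSO and dTAG, had 2 libraries after 24 h. The parental WT line had 2 libraries with LIF and 2 after 5 days without it. Counted reads per library were 7221451 and 11447468 for DMSO, 9430702 and 9179808 for dTAG, 11308343 and 8323172 for WT with LIF, and 11417897 and 7238413 for WT without LIF. Replicates correlated at r = 0.992 to 0.993 across genes, on log2 CPM. The first principal component, with 68.6% of the variance, set the libraries without LIF apart from the other 6. The second, with 21.1%, ran from WT with LIF through DMSO to dTAG.

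Pou5f1, which encodes OCT4, was read at 77.5 and 77.8 CPM in the DMSO libraries and at 84.6 and 90.2 CPM in the dTAG libraries. Its log2 fold change with dTAG was 0.17 (SE 0.10, edgeR adjusted p = 0.18), so a change in transcript level was not called; the treatment acts on the protein, which was not measured here. The call of this small increase was passed with a replicate block (adjusted p = 0.044), without WT LIF replicate 2 (adjusted p = 0.048) and with only the 4 OCT4-FKBP libraries (adjusted p = 0.027). The parental line held 425 and 336 CPM of Pou5f1 with LIF and 205 and 170 CPM without it. Pou5f1 has 2 accessions, and the larger part of its counted reads came from sequence particular to NM_013633.

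**Figure D1:**
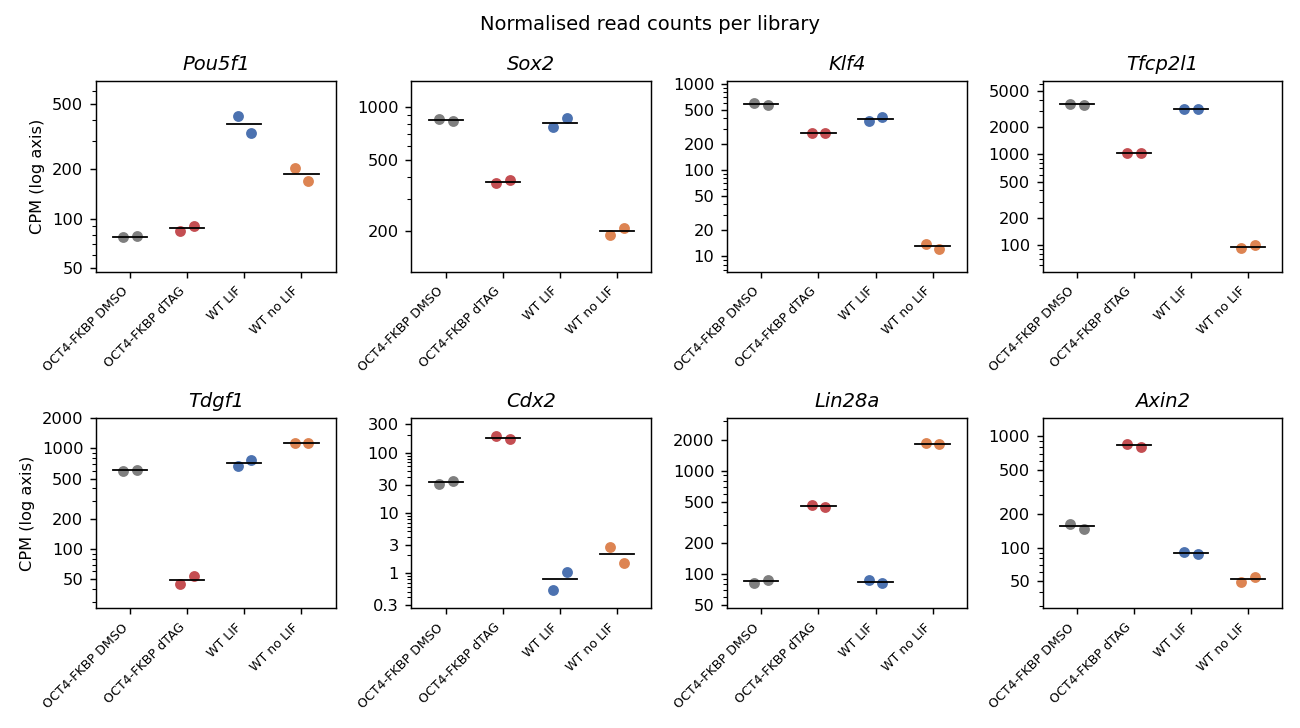
Normalised read counts (CPM, log axis) of 8 genes in each library; dots are the 2 libraries of a group and the line is their mean. Sox2, Klf4, Tfcp2l1 and Tdgf1 were lower in dTAG than in DMSO, Cdx2, Lin28a and Axin2 were higher, and Pou5f1 lay between 77.5 and 90.2 CPM in all 4 OCT4-FKBP libraries.

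The first comparison asked which transcripts changed in the OCT4-FKBP line after 24 h with dTAG, called OCT4 degradation here. No untagged cells received dTAG, so effects of the compound itself cannot be told apart from those of OCT4 loss. Core and naive pluripotency genes fell and trophoblast genes rose, while formative genes did not move as a set. Sox2, the DNA-binding partner of OCT4, went from 845 ± 13.6 CPM in DMSO to 377 ± 9.17 CPM with dTAG (SD, n = 2), a 2.24-fold decrease (edgeR adjusted p = 7.8e-15). Tdgf1, the Nodal co-receptor Cripto, went from 603 ± 2.36 to 49.9 ± 6.16 CPM, 12.1-fold lower (edgeR adjusted p = 1.3e-22). Cdx2, a regulator of trophectoderm, went from 32.9 ± 3.03 to 180 ± 16.6 CPM, 5.43-fold higher (edgeR adjusted p = 5.2e-17). In edgeR's quasi-likelihood test, 4175 of 10311 genes passed an adjusted p of 0.05, 2077 higher and 2098 lower, and 599 and 716 of these changed at least 2-fold.

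Among the genes with the largest increases, Cyp1b1, a cytochrome P450, rose from 1.44 ± 0.451 to 146 ± 1.07 CPM (log2 fold change 6.58, SE 0.16, edgeR adjusted p = 1.2e-21). Ihh, a hedgehog ligand, rose from 0.29 ± 0.212 to 24.7 ± 0.468 CPM. Dkk4, a secreted Wnt antagonist, had 1 read in DMSO and 301 with dTAG, a ratio of 307 with an exact interval of 54.6 to 12100. Osbp2 had 3 reads in DMSO and 198 with dTAG, a ratio of 67.2 (interval 22.7 to 329). Sprr2a3, a member of a gene family with near-identical copies among which reads could be split, rose 44.8-fold. Of the largest decreases, Sfrp1, another secreted Wnt antagonist, fell from 507 ± 9.21 to 12.6 ± 2.14 CPM (log2 fold change -5.33, SE 0.08, edgeR adjusted p = 3.1e-25). Aoah, a lipid hydrolase, fell from 85.2 ± 5.15 to 0.552 ± 0.317 CPM, and Ntn1, the guidance cue netrin-1, from 14.3 ± 0.429 to 0.385 ± 0.0743 CPM. Olig2, a neural bHLH factor, had 321 reads in DMSO and 1 with dTAG, a ratio of 315 (interval 56.2 to 12500). Rbfaos, an antisense transcript, fell 45.3-fold, but its reads cannot be told apart from those of its sense partner where the strand setting is unknown.

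The core pluripotency list fell with OCT4 degradation. Of its 17 tested members, 13 fell, 2 rose and 2 did not pass; adjusted over the list alone, 14 fell and 2 rose. The median log2 fold change was -1.23 (camera adjusted p = 1.3e-20). Lin28a, an RNA-binding protein that blocks let-7 processing, went against the list and rose from 84.8 ± 4.4 to 457 ± 18.8 CPM. Of 16 naive pluripotency genes, 14 fell and 0 rose (15 and 0 adjusted over the list alone), with a median of -1.12 (camera adjusted p = 1.6e-19). Tfcp2l1, a naive transcription factor, went from 3570 ± 35.5 to 1030 ± 0.909 CPM, and the log2 fold changes of Klf2 and Klf4 were -2.22 (SE 0.08) and -1.11 (SE 0.06). Nanog and Esrrb, with 0 and 1 reads over all libraries, could not be tested. The LIF-STAT3 list, which shares Klf4, Tfcp2l1 and Gbx2 with the naive list, also fell, with 10 of 13 members lower and 3 higher in both adjustments (median -0.46, camera adjusted p = 3.5e-04). Of 15 formative and primed genes, 6 fell and 2 rose (7 and 3 adjusted over the list alone); the log2 fold changes of Zic2 and Sox11 were -2.05 and 2.60, and the set did not pass (camera adjusted p = 0.42).

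Trophoblast genes rose: of 21 tested, 15 rose and 3 fell (16 and 4 adjusted over the list alone), with a median of 1.70 (camera adjusted p = 8.4e-11). Besides Cdx2, the ERK phosphatase gene Dusp9 rose from 78.4 ± 2.25 to 246 ± 8.44 CPM. Primitive streak genes fell as a set, with 6 of 15 lower and 2 higher (7 and 2 adjusted over the list alone; median -0.75, or -0.39 with groups at 0 reads set to their floor; camera adjusted p = 8.9e-07). Its members of smallest adjusted p were Tdgf1, also on the core list, and Lefty2, a Nodal antagonist, which fell from 294 ± 5.23 to 10.6 ± 3.53 CPM. Lefty1, Lefty2 and Nodal are also on the TGF-beta, Nodal and BMP list, so these sets are not independent. Another 7 streak genes did not pass. Of 11 primitive endoderm genes, 4 rose and 3 fell (5 and 4 adjusted over the list alone); the laminin gene Lamb1 rose 6.58-fold while Lama1 fell 3.43-fold, and the set did not pass (camera adjusted p = 0.30). Of 9 neural genes, 2 rose and 3 fell (3 and 3 adjusted over the list alone), among them Zic1 (log2 fold change 4.41) and Stmn2 (-1.22). Their median of 0.07 and mean of 0.20 were above 0 while camera's direction was down (camera adjusted p = 0.93).

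Wnt targets, a list that shares Cdx2 with the trophoblast list, rose with OCT4 degradation. Of 14 tested, 10 rose and 1 fell in both adjustments, with a median of 1.33 (camera adjusted p = 1.1e-13). Axin2, a feedback inhibitor of the pathway, went from 155 ± 9.85 to 828 ± 31.4 CPM, 5.35-fold higher (edgeR adjusted p = 4.5e-21). Integrated stress response genes fell, 13 of 18 in both adjustments with 0 rising (median -1.11, or -1.05 with floors; camera adjusted p = 1.6e-10), and the mitochondrial folate enzyme Mthfd2 was 2.57-fold lower. Imprinted genes rose as a set, 7 of 12 higher and 1 lower in both adjustments (median 0.87, camera adjusted p = 5.0e-07), led by Phlda2, which went from 15.0 ± 1.42 to 249 ± 10.2 CPM. Of 15 p53 targets, 7 rose and 2 fell in both adjustments, Phlda3 by 2.51-fold upward (median 0.49, camera adjusted p = 0.004). This set call was lost with an estimated correlation (adjusted p = 0.12), while the other 8 lists that passed kept theirs (adjusted p from 0.006 to 0.042 with an estimated correlation).

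The remaining lists did not pass as sets with OCT4 degradation in the planned test. Of 12 FGF-ERK targets, 3 rose and 3 fell in both adjustments; Phlda1 rose from 6.77 ± 0.743 to 173 ± 5.45 CPM, and the median of -0.32 differed in sign from the mean of 0.30 and camera's upward direction (camera adjusted p = 0.30). Of 13 TGF-beta, Nodal and BMP targets, 4 rose and 6 fell (4 and 7 adjusted over the list alone; camera adjusted p = 0.10), with Lefty2 again the member of smallest p. Of 24 Mediator and coactivator genes, 5 rose and 3 fell in both adjustments (camera adjusted p = 0.30). Med12, of the Mediator kinase module, rose 2.32-fold, and Med1 gave 0.47 (SE 0.26, edgeR adjusted p = 0.16). Of 15 germline genes, 4 rose and 3 fell in both adjustments, Rpl10l among the latter (log2 fold change -0.90); the median of 0.25 was positive and camera's direction was down (camera adjusted p = 0.93). Of 19 glycolysis and hypoxia genes, 3 rose, led by the glucose transporter Slc2a1 (2.89-fold), and 5 fell, or 6 adjusted over the list alone (camera adjusted p = 0.99). Of 15 cholesterol synthesis genes, 4 rose and 4 fell in both adjustments, Sqle by 1.34-fold downward; the median of 0.06 was positive and camera's direction down (camera adjusted p = 0.95). G2 and M phase genes fell in 9 of 17 cases and rose in 1 in both adjustments, Cenpf by 1.28-fold downward (camera adjusted p = 0.27). This list passed with no filter (adjusted p = 0.019), without WT LIF replicate 1 (0.044) and with a replicate block (0.044). Of 15 immediate early and heat shock genes, 4 rose and 4 fell in both adjustments, and Atf3 was 7.46-fold lower (camera adjusted p = 0.44). Of 14 fibroblast and smooth muscle genes, 2 rose, Vim by 1.40-fold, and 4 fell, or 6 adjusted over the list alone (camera adjusted p = 0.85). Of the two-cell-like list only 4 genes could be tested; 2 fell, and Pramel7 was 3.51-fold lower.

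The second comparison asked which transcripts changed over 5 days without LIF in the parental line. Naive pluripotency genes fell by large factors, and genes of formative pluripotency, trophoblast, fibroblast and smooth muscle, and FGF-ERK feedback rose. As sets, these 5 lists passed with camera's preset correlation and lost their calls with an estimated correlation (adjusted p = 0.054 to 0.070). Tfcp2l1 went from 3180 ± 37.7 CPM with LIF to 96.0 ± 6.41 CPM without it (SD, n = 2), 33.3-fold lower (edgeR adjusted p = 5.0e-28). Klf4 went from 396 ± 33 to 13.1 ± 1.32 CPM, 29.8-fold lower, and Sox2 from 815 ± 69.2 to 198 ± 11.3 CPM, 4.12-fold lower. Pou5f1 went from 381 ± 63 to 188 ± 24.5 CPM, 2.02-fold lower (edgeR adjusted p = 3.5e-11). In edgeR's quasi-likelihood test, 7056 of 10311 genes passed, 3509 higher and 3547 lower, and 1712 and 1750 of these changed at least 2-fold.

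The genes with the largest fitted increases had no read in either library with LIF, so only a lower bound of each fold is measured and their order is not. Gbp2b, an interferon-induced GTPase of a family with similar copies, had 664 reads without LIF and was at least 230-fold higher. Sel1l3 was at least 159-fold higher, the imprinted RNA H19 at least 127-fold, the chloride channel gene Clic5 at least 120-fold and Tmem154 at least 110-fold. Obox6, a homeobox gene of a repeated family, had 256 reads with LIF and 0 without, at least 82.0-fold lower. Htr5a, a serotonin receptor, had 335 reads with LIF and 1 without, a ratio of 322 (interval 57.4 to 12700). Bhmt, an enzyme of methionine metabolism, gave a ratio of 215 (38.2 to 8540), Hoxb13 of 196 (34.8 to 7780) and Mst1 of 169 (46.5 to 1400), each with 1 or 2 reads left without LIF.

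All 16 tested naive genes fell in both adjustments, with a median log2 fold change of -3.09 (camera adjusted p = 9.8e-24; adjusted p = 0.054 with an estimated correlation). All 15 formative and primed genes rose in both adjustments, with a median of 3.86 (camera adjusted p = 2.3e-13; adjusted p = 0.058 with an estimated correlation). Pim2, a kinase, rose from 12.8 ± 0.0775 to 285 ± 17.2 CPM and Sox11 from 23.4 ± 1.36 to 249 ± 4.32 CPM. Core pluripotency genes went both ways, 7 up and 7 down of 17 in both adjustments. Lin28a rose from 84.6 ± 4.05 to 1830 ± 46.7 CPM while Fgf4, the autocrine FGF ligand of ES cells, fell 5.01-fold. The mean of this list was 0.25, its median -0.00 and camera's direction up (camera adjusted p = 0.66). Of 13 LIF-STAT3 genes, 8 fell, Klf4 and Tfcp2l1 among them, and 2 rose in both adjustments (median -1.05, camera adjusted p = 6.6e-11; adjusted p = 0.054 with an estimated correlation).

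Of 21 trophoblast genes, 17 rose and 3 fell in both adjustments (median 3.32, camera adjusted p = 2.3e-14; adjusted p = 0.070 with an estimated correlation). The 3 that fell were Tfap2a (log2 fold change -3.79), Tfap2c (-2.31) and Tead4 (-1.5). Gata2, Gata3 and Elf5 were among the listed genes that could not be tested. The keratin genes Krt18 and Krt8, which simple epithelia also express, went from 7.84 ± 0.225 to 851 ± 39.1 CPM and from 10.1 ± 1.11 to 499 ± 30.9 CPM. Of 14 fibroblast and smooth muscle genes, 11 rose and 2 fell in both adjustments (median 1.81, camera adjusted p = 3.6e-04; adjusted p = 0.058 with an estimated correlation), and the smooth muscle gene Tagln rose 376-fold, from 1.94 ± 0.25 to 744 ± 27.3 CPM. Of 15 primitive streak genes, 11 rose and 3 fell in both adjustments (median 2.60, camera adjusted p = 0.023; adjusted p = 0.26 with an estimated correlation), a call also lost with at least 5 CPM in 2 libraries (median 1.89, adjusted p = 0.079). The Nodal antagonist Lefty1 rose 17.0-fold and Lefty2 fell 3.73-fold. Of 11 primitive endoderm genes, 6 rose and 3 fell (6 and 4 adjusted over the list alone; median 0.95, camera adjusted p = 0.10). With only 1-accession genes the primitive endoderm list passed (median 2.79, camera adjusted p = 0.050, just under the threshold before rounding). The list also passed without WT no LIF replicate 1 (median 2.03), a fit that left 1 library in that group. Of the 11 genes, the collagen gene Col4a2 rose 27.2-fold and Lama1 fell (log2 fold change -2.49). Of 9 neural genes, 3 rose and 3 fell in both adjustments (camera adjusted p = 0.91), with Sox1 2.30-fold higher and Pou3f2 6.45-fold lower.

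FGF-ERK feedback targets rose, 10 of 12 with 1 lower in both adjustments (median 2.06, camera adjusted p = 1.0e-06; adjusted p = 0.058 with an estimated correlation). Dusp6, an ERK phosphatase, went from 7.34 ± 1.23 to 330 ± 4.14 CPM, 44.2-fold higher (edgeR adjusted p = 5.1e-25). Of 13 TGF-beta, Nodal and BMP targets, 9 rose, Lefty1 among them, and 2 fell, Lefty2 among them, in both adjustments (median 1.19, camera adjusted p = 0.001; adjusted p = 0.26 with an estimated correlation). Integrated stress response genes fell, 14 of 18 with 0 rising (15 adjusted over the list alone; median -1.02, camera adjusted p = 2.2e-05; adjusted p = 0.058 with an estimated correlation), and Nupr1 was 26.8-fold lower. Wnt targets went both ways, 4 up and 5 down of 14 in both adjustments (camera adjusted p = 0.66), and Cdx1 was 33.3-fold lower.

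The other lists did not pass as sets after LIF withdrawal in the planned test. Imprinted genes rose in 7 and fell in 3 of 12 cases in both adjustments, Plagl1 by 8.56-fold downward (camera adjusted p = 0.11). The imprinted list passed with no filter (adjusted p = 0.030), without WT no LIF replicate 1 (0.034) and with only the 4 libraries of the comparison (0.035). Of 24 Mediator and coactivator genes, 10 rose and 4 fell in both adjustments (camera adjusted p = 0.37). Med14 rose 3.57-fold and Med1 gave 0.41 (SE 0.20, edgeR adjusted p = 0.077). Of 15 germline genes, 8 rose and 5 fell (9 and 5 adjusted over the list alone), Rpl10l by 19.2-fold downward; the median of 1.01 was positive and camera's direction down (camera adjusted p = 0.48). Of 15 p53 targets, 5 rose, with Pmaip1 5.90-fold higher, and 7 fell in both adjustments; the median of -0.19 was negative and camera's direction up (camera adjusted p = 0.45). Of 19 glycolysis and hypoxia genes, 9 rose and 6 fell in both adjustments, Slc2a1 by 4.41-fold upward (camera adjusted p = 0.37). Of 15 cholesterol synthesis genes, 5 rose and 6 fell in both adjustments, Insig1 by 2.33-fold downward (camera adjusted p = 0.89). G2 and M phase genes rose in 9 of 17 cases and fell in 1 in both adjustments, Mki67 by 1.63-fold upward (camera adjusted p = 0.36). Of 15 immediate early and heat shock genes, 6 rose, or 5 adjusted over the list alone, and 3 fell; Jun was 8.48-fold higher (camera adjusted p = 0.48). Of 4 tested two-cell-like genes, 1 rose and 2 fell (2 and 2 adjusted over the list alone), Pramel7 by 24.2-fold downward.

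**Figure D2:**
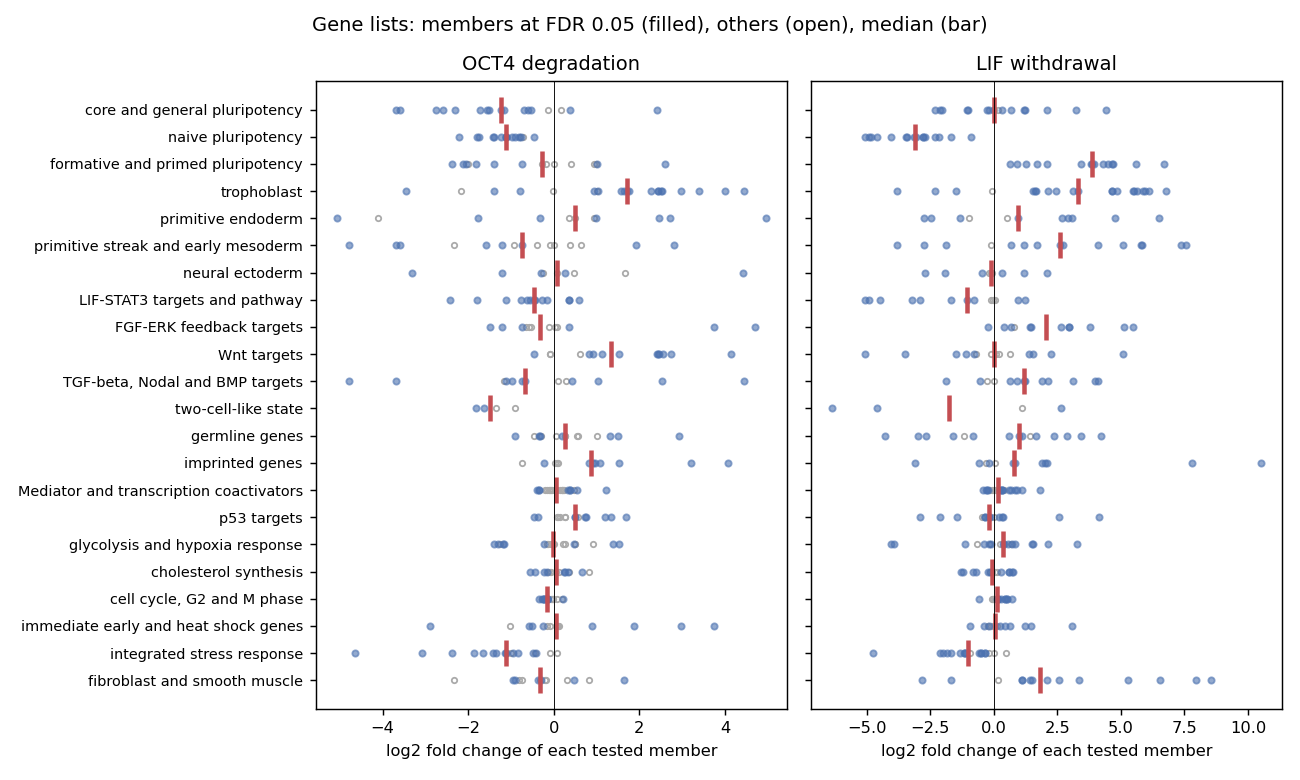
Log2 fold changes of the tested members of each gene list with OCT4 degradation (left) and LIF withdrawal (right); filled dots passed an adjusted p of 0.05, open dots did not, and the bar is the list's median. Naive genes lie below 0 in both panels (medians -1.12 and -3.09), and Wnt targets have medians of 1.33 and -0.01.

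The third comparison asked whether the responses differed between OCT4 degradation and LIF withdrawal. Both lowered Sox2, Klf4 and Tfcp2l1 and both raised Lin28a, but many genes responded differently. The test of the difference passed for 5671 of 10311 genes in edgeR, 2946 with a higher and 2725 with a lower change under OCT4 degradation. This balance turned around with RLE size factors (2782 and 2891) and in DESeq2 (2276 and 2423). Khdc1a, of a family with similar copies, rose with dTAG (log2 fold change 2.40, SE 0.12) and had 77 reads with LIF against 0 without, at least 24.7-fold lower. Bhmt likewise rose with dTAG (1.64, SE 0.12) while it fell without LIF. Htr5a gave 0.25 (SE 0.14) and Grin1, a glutamate receptor subunit, -0.23 (SE 0.20) with dTAG, neither called, while Grin1 was at least 45.1-fold lower without LIF. Sgcz was lower in both, with a log2 fold change of -0.73 (SE 0.20) with dTAG, and at least 47.7-fold without LIF. In the other direction, Trim67 rose from 14 to 4196 reads without LIF and had 13 reads in DMSO and 4 with dTAG. St8sia3 rose from 2 to 381 reads without LIF, a ratio of 198 (interval 54.5 to 1640), and had 5 reads in DMSO and 1 with dTAG. Gbp2b and Sel1l3, absent from the counts with LIF, had at most 6 reads in either OCT4-FKBP group. The call of the difference was lost for St8sia3, Gbp2b and Sel1l3 without OCT4-FKBP DMSO replicate 2. Both DMSO libraries together held 5, 1 and 2 reads of these genes, so the lost calls say little about a difference. Cell line, time and treatment all differ between the arms.

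**Figure D3:**
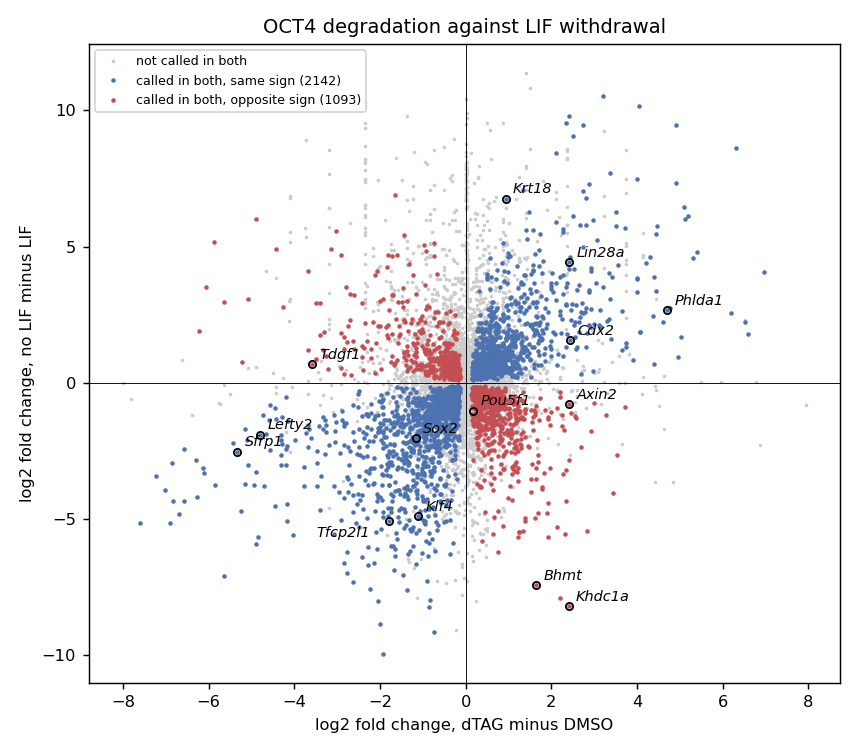
Log2 fold changes of all 10311 tested genes with OCT4 degradation (x axis) and LIF withdrawal (y axis); blue dots were called in both with the same sign, red dots in both with opposite signs, grey dots not in both. There were 2142 blue and 1093 red genes, with Tdgf1, Axin2, Bhmt and Khdc1a among the red.

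Across the 10311 genes, the log2 fold changes of both responses correlated with a Pearson r of 0.23 and a Spearman rho of 0.23; genes are not independent replicates and no p-value is given. Of genes called in both, 2142 changed in the same direction and 1093 in opposite directions. Genes higher in both numbered 960, against 706.8 for independent lists of these sizes, and genes lower in both 1182, against 721.7. Genes higher with dTAG and lower without LIF numbered 607, against 714.5, and the reverse 486, against 714.0. Tdgf1 was 12.1-fold lower with dTAG and had a log2 fold change of 0.68 without LIF, and Axin2 was 5.35-fold higher with dTAG and had one of -0.79 without LIF.

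The fourth comparison set the control groups side by side, the tagged line in DMSO against the parental line with LIF. Cdx2 was at 32.9 ± 3.03 CPM in the tagged line and at 0.794 ± 0.374 CPM in the parental line, 43.1-fold higher (log2 fold change 5.43, SE 0.23, edgeR adjusted p = 1.5e-15). Mfsd4b1 was 13.2-fold higher, and the antisense transcript Rbfaos was higher (log2 fold change 3.80), with the strand caution above. Slfn9, of a family with similar copies, was 11.7-fold lower, the immediate early gene Egr1 10.6-fold lower and Sox1 6.38-fold lower; Egr1 varied in the parental line (31.4 ± 15.3 CPM). Pou5f1, the tagged gene, was lower in the tagged line, with a log2 fold change of -2.30 (SE 0.09, edgeR adjusted p = 3.5e-16). Its counted reads cover part of the gene, and whether that part holds the tag insertion was not analysed here. In edgeR, 4191 of 10311 genes passed, 1908 higher and 2283 lower, and 360 and 620 of these differed at least 2-fold. The excess of lower genes depended on the setting: the DESeq2 test gave 1509 higher and 1409 lower, and edgeR without WT no LIF replicate 2 gave 2109 and 2030. The tag, the clone, DMSO and any culture batch differ together between these groups.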

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

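The trophoblast mixture test, whose rule was also changed once its result was known, and both tests of the FGF-ERK pattern below were chosen after the results were seen. The difference between the 2 responses stood out because a direct test of it passed for 5671 genes, and because 1093 genes called in both responses moved in opposite directions with the difference also called. The fitted log2 difference (dTAG response minus LIF withdrawal response) was 10.60 for Khdc1a, 9.06 for Bhmt, 8.85 for Grin1, 8.43 for Sgcz and 8.26 for Htr5a. It was -9.96 for Gbp2b, -9.89 for Trim67, -9.51 for St8sia3 and -9.33 for Sel1l3. These fitted values rest on groups with 0 to 14 reads and depend on edgeR's prior count, so they are no bounds. Without OCT4-FKBP DMSO replicate 2, the difference was no longer called for Gbp2b (-7.58), St8sia3 (-5.11) or Sel1l3 (-6.11). Since DMSO held at most 5 reads of each over both libraries, these lost calls say little about a difference. Outside the gene counts, the share of ambiguous reads was higher in both libraries without LIF, at least 42.9%, than in those with LIF, 42.2% and 42.5%. It was also higher in both dTAG libraries, at least 42.5%, than in both DMSO libraries, 42.2%.

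The tagged line in DMSO held fewer Pou5f1 reads and more Cdx2 reads than the parental line. The groups also differ by clone, DMSO and any culture batch. These, and a tag insertion within the counted part of Pou5f1, were not tested as causes of this pattern. Depth or scaling argues poorly for it, since over the alternatives Pou5f1 stayed at or below -2.11 and Cdx2 at or above 4.95 on the log2 scale, both called. Partial loss of OCT4 function in the tagged line stays open. Of the 1315 genes changed at least 2-fold by degradation, 54.4% (exact interval 51.7% to 57.2%) had the same sign here. This lay just under the 55% set before this test was run. The interval treats genes as independent, which they are not. Simulated groups without any effect, sharing the DMSO libraries, gave 20.3%. Their largest changes are noise, so this share is no reference for called 2-fold changes. Of the 3462 genes changed at least 2-fold by LIF withdrawal, 54.0% also had the same sign here. That comparison shares the WT LIF libraries with this one. Naive genes, which fell with degradation, were higher here (median log2 fold change 0.17, camera adjusted p = 0.011; adjusted p = 0.17 with an estimated correlation), but the shared DMSO libraries favour opposite signs, so this decides nothing, and core pluripotency genes went both ways, 6 higher and 5 lower (camera adjusted p = 0.43). Differentiated trophoblast cells mixed into the tagged culture also stay open: of 15 markers that rose with degradation 7 were higher and 3 (Krt7, Ascl2 and Esx1) lower, which by the first rule (2 lower markers) argued against a mixture, but a minimum of 5 CPM, added after that result because counts near the floor exclude little, left 1, Esx1.

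Several genes known to be abundant in these cells, such as Nanog and Gapdh, had almost no reads. A candidate explanation is that reads in exons shared by several accessions were set aside as ambiguous. Among ribosomal protein genes, 98.2% of 55 with 1 accession but 47.1% of 17 with more reached 100 reads over the 8 libraries (Fisher's exact test, two-sided, p = 2.5e-06), which is consistent with it. No biological explanation was tested.

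FGF-ERK feedback genes such as Dusp6, Spry4 and Dusp4 rose after LIF withdrawal. One explanation is that the 2i inhibitors, which the labels' growth protocol names, were withdrawn together with LIF. Loss of the GSK3 inhibitor might lower Wnt targets. Of 14 tested, 5 fell (Cdx1, Notum, Apcdd1, Sp5 and Axin2) and 4 rose (T, Sp8, Cdx2 and Ccnd1). They did not move as a set (camera p = 0.60, n = 14 genes), which leaves this explanation open. The other, exit from the naive state over the days without LIF, stays open too. The formative rise and naive fall it needs had been seen before the test was chosen, and a loss of 2i would bring them as well, so they do not decide between the explanations. With an estimated correlation the larger camera p of these lists was p = 0.012 (n = 15 genes), and both set calls were lost after adjustment (adjusted p = 0.058 formative and 0.054 naive).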

How the results depend on the processing

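The alternatives that tested each accession alone or only genes with 1 accession were chosen after seeing the data. Over the alternatives the counts of called genes ranged as follows: 3159 to 4662 for OCT4 degradation, 5809 to 7511 for LIF withdrawal, 4699 to 5801 for the difference and 2918 to 4263 for the control groups. Leaving out single libraries gave 3203 to 4571, 6298 to 7225, 5003 to 5801 and 2990 to 4143; a group then left with 1 library is assumed to vary like the others. Genes called in both responses in the same direction ranged from 1608 to 2239 and in opposite directions from 786 to 1199. The correlation of the responses moved with the genes kept, to 0.162 with no filter and 0.237 with at least 5 CPM in 2 libraries. It was 0.241 in DESeq2, 0.343 with only the 4 libraries of each comparison and 0.178 to 0.257 with single libraries left out; beyond the change of genes tested, the cause was not tested. The lists moved by LIF withdrawal went from 9 to 0 with an estimated correlation (smallest adjusted p = 0.054). At an unadjusted p of 0.05 camera still had 7 of these lists. Members moving together cannot account for every loss. The fibroblast and smooth muscle list had an estimate of 0.0034, below the preset correlation, yet its camera p went from 1.2e-04 to 0.016. The other lists that lost the call had estimates above the preset one, from 0.023 to 0.25. With OCT4 degradation, the core pluripotency list had an estimate of -0.043, yet its camera p went from 6.2e-22 to 4.8e-04. Weaker p-values thus also arose without a positive estimate. A call lost under this setting is therefore no sign by itself that members move together. The cause of the weaker p-values was not tested. The lists moved by OCT4 degradation ranged from 8 to 10. A replicate block, fitted although the replicates share only a number (r of deviations 0.03 and 0.05 for same-numbered libraries), gave 4108, 7054, 5589 and 3257 genes for the 4 comparisons.

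No named gene or list was called in the opposite direction under an alternative, but in all 4 comparisons the larger of the higher and lower counts changed sides with the setting, as in DESeq2. Of 96 named gene results, 4 changed side of the threshold under some alternative: Pou5f1 with degradation and Gbp2b, St8sia3 and Sel1l3 in the difference. Of 42 list results, 13 did, 10 of them through the estimated correlation and the other 3 by passing under some alternative: G2 and M phase with degradation, and primitive endoderm and imprinted genes with LIF withdrawal. The primitive streak list with LIF withdrawal was also lost with at least 5 CPM (adjusted p = 0.079) and with 1-accession genes (0.050). Nanog, Esrrb, Stat3 and Myc cannot be read from these counts.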

Other observations

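The lists had been fixed for the responses; testing them on the difference and on the control groups was chosen after the data were seen. Tested on the difference, 10 of 17 core pluripotency genes had a lower and 4 a higher change with OCT4 degradation than with LIF withdrawal, and of 15 formative genes 13 had a lower and 0 a higher one (camera adjusted p = 3.3e-07 and 1.5e-08; adjusted p = 0.024 for both with an estimated correlation). Naive genes fell less with degradation, 14 of 16 with a higher change and 0 with a lower one (camera adjusted p = 2.4e-10; adjusted p = 0.024 with an estimated correlation). Other lists passed as well. With an estimated correlation the primitive streak, LIF-STAT3 and TGF-beta, Nodal and BMP lists kept the call (camera adjusted p = 0.024 each). The FGF-ERK list lay at 0.050, and the trophoblast, Wnt target and G2 and M phase lists lost the call (0.13, 0.081 and 0.19). Within the core list, Utf1, L1td1 and Foxd3, picked out after their values were seen, fell with dTAG (log2 fold changes -2.75, -2.60 and -3.69) and rose without LIF (2.08, 1.24 and 1.20). Lefty1 likewise fell with dTAG (-3.68) and rose without LIF (4.09).

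Between the control groups, Wnt targets were higher in the tagged line in DMSO, 7 of 14 with 1 lower (camera adjusted p = 2.5e-09; adjusted p = 0.033 with an estimated correlation), with Sp5 at a log2 fold change of 1.54, Rnf43 at 2.25 and Axin2 at 0.79. Integrated stress response genes were lower, 14 of 18 with 0 higher (camera adjusted p = 1.3e-11; adjusted p = 0.033 with an estimated correlation), with Nupr1 at -1.37 and Ddit4 at -1.13. Cholesterol synthesis genes were lower in 12 of 15 cases and higher in 2 (camera adjusted p = 6.8e-04), but that set call was lost with an estimated correlation (adjusted p = 0.17). Wnt targets and integrated stress response genes moved in the same direction with OCT4 degradation, a comparison that shares the DMSO libraries with this one with the opposite sign. Mediator and coactivator genes, 12 of 24 higher and 3 lower (camera adjusted p = 0.015), and germline genes, 5 of 15 higher and 1 lower (camera adjusted p = 0.002), were also higher, both losing the set call with an estimated correlation (adjusted p = 0.17); neither list passed with degradation. Of the lists that passed in both comparisons, 2 had the opposite direction here, which the shared libraries favour: naive genes were higher, 7 of 16 with 1 lower (camera adjusted p = 0.011; adjusted p = 0.17 with an estimated correlation), and p53 targets lower, 8 of 15 with 0 higher (camera adjusted p = 0.014; adjusted p = 0.23 with an estimated correlation). Core pluripotency genes went both ways, 6 higher and 5 lower of 17 (camera adjusted p = 0.43). Across all tested genes, 51.0% had the same sign in both comparisons, with a covariance of 0.012. Simulated groups without any effect gave 33.0% and -0.044. These simulated values reflect noise alone, while 4175 genes were called with degradation and 4191 between the control groups. The simulated values are therefore no reference for unrelated sets of changes.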
